A study of Homo sapiens with 8 samples.

How the data were processed

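Polyadenylated RNA from primary human keratinocytes given 4 mg/mL of IgG overnight was measured in 8 samples, 4 with IgG from bullous pemphigoid patients and 4 with control IgG, as the sample labels state. The authors deposited, per sample, a gene table whose columns, per the file headers, are those of RSEM, with an expected count and a TPM value per gene. Expected counts are estimated numbers of reads per gene, not normalized and not always whole, and the authors deposited them without pooling samples. TPM values, per the file headers, are scaled by transcript length and relative to all transcripts of a sample. RSEM 1.3.3, Bowtie 1.2.3 and the genome build hg38 are listed in the submitters' processing notes. The annotation release, the strand setting and the read layout are not given in the sources used here. Reads of antisense or overlapping genes can therefore not be told apart with certainty. RSEM divides reads that match several genes, so values of near-identical copies (SPRR2, LCE, KRT6, S100A7, AKR1C, metallothionein, HSPA1A and HSPA1B, C4A and C4B) are uncertain singly, and sums over copies are given for LCE, SPRR2 and KRT6.

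Each file held 62696 genes, of which 42339 had a symbol in the table of gene names used. Expected counts were rounded to whole numbers. Genes passing edgeR's filterByExpr with its defaults by group were tested, 14737 in all. Libraries were scaled by TMM factors, and edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model with group as its term (glmQLFit, glmQLFTest). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of single genes are the absolute log2 fold change divided by the square root of the F statistic. An SE given with a list median is that of the group difference in the list's mean log2 CPM, not of the median. It was taken without the length and GC correction. CPM values use the TMM-scaled totals. Gene locations are those of GENCODE release 29 on GRCh38, which covered 14357 of the tested genes, and this release need not be the authors' own. The biological coefficient of variation was 7.46%. Totals of 12673998 to 22325263 counts per sample set the depth, and the upper limit for a gene with 0 counts in a group was taken as 3 counts over the group's summed total, which covers counting error only.

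Before the data were examined, 41 gene lists, the tests, the alternatives, and the rule for naming genes were fixed. The lists cover hemidesmosome, junctions, basal, early and late differentiation, hyperproliferation, cell cycle, cytokines, chemokines, NF-kB, interferons, IL-4 and IL-13, IL-17, JAK-STAT3, complement, inflammasome, Fc receptors, antigen presentation, proteases, immediate early genes, EGFR and MAPK feedback, TGF-beta, NRF2, metallothioneins, heat shock, unfolded protein response, p53, hypoxia, cholesterol, oxidative phosphorylation, lysosome, retinoid and aryl hydrocarbon response, other cell types, and library quality. Lists with at least 3 tested members, 38 in all, were compared with all other genes by camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Where the text says "with an estimated correlation", camera instead estimated the correlation from these samples. Ranges of p for lists cover the other camera fits on all or 7 samples, and fry is kept apart.

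The rule for named genes took the 12 largest rises and the 12 largest falls among called genes with a symbol, a mean log2 CPM of at least 1 and groups that do not overlap. It also took up to 4 called members of each list by smallest p, or the 2 most expressed where none was called, and always COL17A1, DST, IL6, CXCL8, CCL26, MMP9, FCGRT and PLAU. Some genes the rule took are not reported here. HLA genes and genes whose level follows a common germline deletion are not named singly. Members of a list's small counts (5 or fewer) that fall outside the rule are named too, and these were chosen after their values were seen. They are AREG, ATG7, BCL2L11, BTG2, CASP1, CASP14, CAT, CCL20, CHORDC1, DNAJA1, DSC1, DSG1, DUSP4, EGFR, EIF2AK2, EPGN, EREG, FERMT1, FETUB, FOSL2, GADD45A, HBEGF, HMOX1, HSP90AA1, HSPA1A, ICAM1, IDI1, IFITM3, IL18, IL4R, ISG15, ITGA2, KLK5, KLK7, LAMA3, LCE2B, MSMO1, MT-RNR1, NLRP1, NPC1, OAS2, SERPINB3, SLC7A11, SPINK5, SPRR1B, SREBF2, TGFA, TRAF1, TRIM22 and UBE2L6. Further genes of 3 lists written for the hypotheses at the end fall outside the rule as well. So do SPRR2A, SPRR2D and list members named with counts too low to test.

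Alternatives tried were DESeq2 size factors (RLE), no low-count filter, a stricter filter, the replicate number as a block, each sample left out in turn, DESeq2 1.42.0, voom with sample quality weights, an adjusted p under 0.10, a fold bound of 1.5, limma-trend on log2(TPM + 1), camera with an estimated correlation, and fry. Fits without Ctrl-IgG 1 and 2 or without Ctrl-IgG 3 and 4 were added after seeing the data. A correction for gene length and GC content was added after seeing the data too, with both values at hand for 97.4% of tested genes. The procedure was tested on simulated data drawn from these samples' means and library sizes, 14587 genes with 200 changed by known folds and the members of the junction list raised by 1.5-fold. It recovered 16% of 1.2-fold, 66% of 1.5-fold, 84% of 2-fold and 100% of 4-fold changes. Far fewer genes were changed there than were called in the data, so these shares need not hold for the data. Of its 164 calls, junction members included, 10 were simulated without change (6.1%). With no change simulated it called 0 genes by edgeR's quasi-likelihood test. The FPKM column of the files was not used here.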

Results

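Primary human keratinocytes from skin were cultured in EpiLife medium with a growth supplement and given 4 mg/mL of affinity-purified IgG overnight. The IgG came from people with bullous pemphigoid (BP-IgG, 4 samples) or from controls (Ctrl-IgG, 4 samples), and polyadenylated RNA was sequenced. Bullous pemphigoid is a blistering disease with autoantibodies against hemidesmosomal proteins, which anchor basal keratinocytes to the basement membrane. The comparison asks how the transcriptome of keratinocytes given patient IgG differs from that of keratinocytes given control IgG. The deposited counts summed to 16167646, 18306669, 22325263 and 22055053 in BP-IgG 1 to 4, and to 19748317, 20336080, 19861692 and 12673998 in Ctrl-IgG 1 to 4. Values below are means ± SD in CPM (counts relative to the scaled total of a sample) over the 4 samples of a group, BP-IgG first. Numbers in parentheses after a gene are log2 fold changes of BP-IgG over Ctrl-IgG, where a positive value is higher with BP-IgG.

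The lists of late differentiation genes and of EGFR ligands and MAPK feedback genes were lower in cells given BP-IgG. The oxidative stress list and the retinoid and aryl hydrocarbon list were higher. Each of these 4 calls was lost with an estimated correlation (camera adjusted p = 0.13 for each). The filaggrin relative FLG2, a protein of the cornified layer, was at 2.13 ± 0.293 against 48.7 ± 0.715 CPM (log2 fold change -4.50, SE 0.08, edgeR adjusted p = 3.6e-12). KRT4, a keratin of mucosal epithelia, was at 22.5 ± 10.2 against 0.799 ± 0.136 CPM (log2 fold change 4.79, SE 0.37, edgeR adjusted p = 1.9e-06). Across 14737 tested genes, 1810 were higher and 1553 lower with BP-IgG by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3363 in all. Most of these changes were small, with 226 rises and 218 falls of at least 2-fold and 2396 changes under 1.5-fold. Rises made up 53.8% of the calls, whereas on the authors' TPM scale limma called 779 genes higher and 1296 lower, 37.5% higher. The median log2 change there was -0.07 over 13378 tested genes, in a fit that differs in scale, transform, test and gene set at once. In 25.3% of tested genes all 4 samples of a group lay above all 4 of the other, against 2.86% by chance. Nothing in the labels says that the samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

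The 12 largest rises among expressed genes included KRT4 (4.79), IGFBP3 (3.87), LY6D (3.40) and CYP1B1 (3.27), followed by PHYHIP (3.08), WNT10A (2.85), RHCG (2.73), WNT4 (2.72), KANK4 (2.65), PDZK1IP1 (2.52), VSIR (2.51) and ACKR3 (2.45). IGFBP3 encodes a binding protein of insulin-like growth factors, WNT4 and WNT10A encode WNT ligands, and ACKR3 a chemokine-scavenging receptor. The 12 largest falls were KPRP (-4.57), FLG2 (-4.50), HRNR (-3.99), SPRR2B (-3.49), SPRR2G (-3.45) and LCE1C (-3.03), then SPRR2E (-2.99), TCHH (-2.89), SMPD3 (-2.82), ACP7 (-2.79), KRT2 (-2.71) and PRR9 (-2.58). KPRP, FLG2, HRNR, SPRR2B, SPRR2G, LCE1C, SPRR2E, TCHH and PRR9 lie in the epidermal differentiation complex on chromosome 1, KRT2 is a keratin of upper epidermal layers, and SMPD3 encodes a neutral sphingomyelinase. In GRCh38, FLG2 spans chromosome 1, 152348735 to 152360006, KPRP chromosome 1, 152759561 to 152762052 and KRT4 chromosome 12, 52806549 to 52814551. Each of these 24 genes had adjusted p of 0.00011 or less by edgeR's quasi-likelihood test. For some, Ctrl-IgG 1 and 2 differed from Ctrl-IgG 3 and 4, so the fold change depends on the controls. LY6D was at 4.33 and 6.31 CPM in the former pair and at 13.65 and 17.9 in the latter. WNT10A was at 4.58 and 4.33 CPM and at 11.8 and 9.85. WNT4, PHYHIP, PDZK1IP1, RHCG and TCHH were also higher in Ctrl-IgG 3 and 4, and ACP7 and PRR9 lower. CYP1B1, VSIR and ACKR3 did not part in this way.

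**Figure D1:**
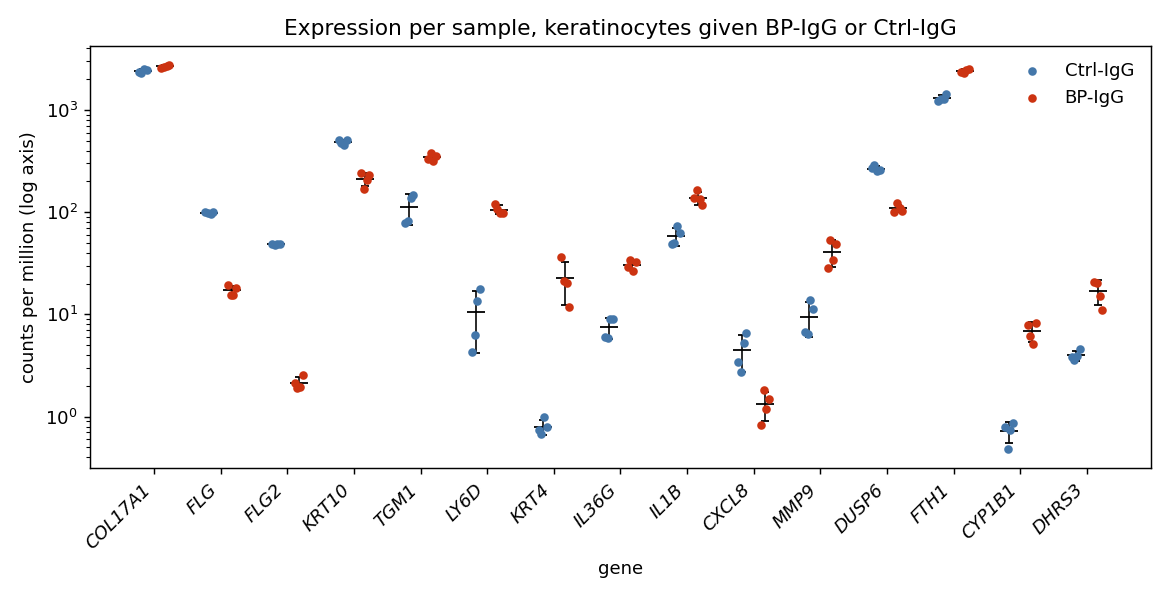
CPM of 15 genes on a log axis, with 1 point per sample, blue for Ctrl-IgG and red for BP-IgG, and black bars for the mean and SD of 4 samples. FLG2 lies at 2.13 CPM with BP-IgG against 48.7 with Ctrl-IgG, and KRT4 at 22.5 against 0.799.

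Counts of the pemphigoid antigen genes, each taken over the whole gene, differed little between groups. COL17A1, which encodes the BP180 antigen (ENSG00000065618 in the files, chromosome 10, 104031286 to 104085957), was at 2668 ± 67.3 against 2401 ± 106 CPM (log2 fold change 0.15, SE 0.04, edgeR adjusted p = 0.027). That call was lost without BP-IgG 2, BP-IgG 3, BP-IgG 4, Ctrl-IgG 1 or Ctrl-IgG 2, with adjusted p = 0.072, 0.087, 0.101, 0.058 and 0.091, and with the replicate block (0.051), in a range of 0.0014 to 0.101 over all alternatives. DST, whose epithelial product is the BP230 antigen (chromosome 6, 56457987 to 56954628), was at 1132 ± 121 against 1362 ± 223 CPM (log2 fold change -0.27, SE 0.10, adjusted p = 0.080) and did not pass the test. These counts cover all transcripts of DST, so the BP230 transcript was not measured apart. DST passed without BP-IgG 3 or Ctrl-IgG 2, with no low-count filter and with the replicate block, with adjusted p = 0.042, 0.026, 2.3e-06 and 0.0086, in a range of 2.3e-06 to 0.20. The groups overlapped for DST. With no filter its log2 change was -0.27 as in the main fit, so the lower p does not reflect a larger change. In the hemidesmosome and basement membrane list, of 18 measured members, 4 rose and 3 fell (5 and 6 adjusted over the list alone). The integrin subunits ITGB4 and ITGA6, partners in the hemidesmosome, fell (-0.56 and -0.44), as did the laminin chain LAMA3 (-0.22). COL17A1 rose with FERMT1 (0.19), CD151 (0.25) and HSPG2 (0.51), but CD151 was no longer past the test after a length and GC correction (adjusted p = 0.14, range 4.4e-05 to 0.14). As a set this list did not pass (camera adjusted p = 0.65).

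Junction genes were higher in the cells given BP-IgG. In the desmosome and cell junction list, of 22 measured members, 13 rose and 2 fell (13 and 3 adjusted over the list alone). The gap junction genes GJB6 (0.73) and GJA1 (0.31) rose, and so did the desmosomal cadherin DSC2 (0.69) and E-cadherin, CDH1 (0.30). The exceptions were DSC1 (-0.76) and DSG1 (-0.28), desmosomal cadherins of differentiating layers, which fell. The list passed its test (camera adjusted p = 0.00011, 1e-10 to 0.00038 over the other alternatives and adjusted p = 0.39 with an estimated correlation). The junction mean log2 CPM was 7.932 and 7.885 in Ctrl-IgG 1 and 2, 8.146 and 8.167 in Ctrl-IgG 3 and 4, and 8.242 to 8.325 with BP-IgG. Among basal keratinocyte genes, of 16 measured members, 7 rose and 4 fell (7 and 6 adjusted over the list alone), with KRT15 (1.95), CXCL14 (0.76) and ASS1 (0.75) among the rises. ITGB4 (-0.56), ITGA2 (-0.52), ITGA6 (-0.44) and EGFR (-0.37) were the falls, and the list did not pass (camera adjusted p = 0.73).

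Late differentiation genes fell together in cells given BP-IgG, while early differentiation genes went both ways. In the late differentiation and cornified envelope list, of 34 measured members, 5 rose and 21 fell (6 and 21 adjusted over the list alone), with a median log2 change of -1.04. The falls included filaggrin, FLG (17.2 ± 1.93 against 99.02 ± 2.001 CPM, chromosome 1, 152302175 to 152325203), hornerin, HRNR (1.51 ± 0.465 against 23.5 ± 2.82 CPM), and LCE2B (-5.90), which was picked after its value was seen. LCE2B was near the floor with BP-IgG, at 0.0706 ± 0.0907 against 4.29 ± 0.823 CPM. Members that rose were KLK5 (1.09), CASP14 (0.56), SPRR1B (0.53), KLK7 (0.42) and SPINK5 (0.31): kallikrein proteases, a caspase that processes filaggrin, a cornified envelope precursor and a protease inhibitor. The CPM summed over the list was 2682 ± 136 against 2439 ± 152, opposite in direction to the median, and SPRR1B alone was at 1363 ± 76.2 against 943 ± 130 CPM. The list passed its test (camera adjusted p = 3.8e-09, 8e-14 to 4.6e-06 over the other alternatives and adjusted p = 0.13 with an estimated correlation). Reads can be divided unevenly among near-identical copies, so the copies were also summed. The 18 LCE genes together were at 12.7 ± 2.70 against 86.1 ± 11.5 CPM, and the 7 SPRR2 genes at 80.0 ± 10.2 against 156 ± 9.19 CPM. In both sums all 4 BP-IgG samples lay below all 4 Ctrl-IgG samples. HRNR stood higher in Ctrl-IgG 3 (27.7 CPM) than in the other Ctrl-IgG samples (21.6 to 22.4 CPM).

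In the early keratinocyte differentiation list, of 18 measured members, 7 rose and 3 fell (8 and 3 adjusted over the list alone). TGM1, the transglutaminase that cross-links the envelope, rose (344 ± 26.0 against 112 ± 36.8 CPM, log2 fold change 1.62, SE 0.17, edgeR adjusted p = 2.7e-05), as did LY6D (3.40) and CALML3 (0.84). Within the controls TGM1 was at 78.7 and 82.95 CPM in Ctrl-IgG 1 and 2 and at 139 and 149 in Ctrl-IgG 3 and 4. Suprabasal keratin KRT10 fell (211 ± 32.0 against 484 ± 26.0 CPM, log2 fold change -1.2, SE 0.09, edgeR adjusted p = 1.5e-06), and so did DSC1 (-0.76) and DSG1 (-0.28). The list did not pass (camera adjusted p = 0.086), but passed without BP-IgG 3, Ctrl-IgG 3 or Ctrl-IgG 4 and with no filter (camera adjusted p = 0.024, 0.031, 0.016 and 0.0037, in a range of 0.0037 to 0.16). Keratins and proteins of wounded or hyperproliferative epidermis rose: of 11 measured members, 10 rose and 0 fell (10 and 1 adjusted over the list alone). KRT17 (0.52) and KRT6A (0.46) and the calprotectin genes S100A8 (1.49) and S100A9 (1.18) led this list by p (camera adjusted p = 7.1e-06, 8.7e-14 to 5e-05 over the other alternatives and adjusted p = 0.28 with an estimated correlation). The mean log2 CPM of this list was 8.409 and 8.421 in Ctrl-IgG 1 and 2, 8.771 and 8.847 in Ctrl-IgG 3 and 4, and 9.138 to 9.259 with BP-IgG, and S100A8 was at 53.3 and 54.45 CPM in the former control pair and at 91.5 and 105.8 in the latter. SERPINB3 (-0.19) was the member that did not pass over all tested genes. The 3 KRT6 copies summed to 18010 ± 595 against 13080 ± 1556 CPM. Of 33 cell cycle genes, AURKA fell (-0.25, adjusted p = 0.0496) and none rose, with 0 past edgeR's test when adjusted over the list alone. The list still passed as a set (camera adjusted p = 0.026, 0.0011 to 0.18 over the other alternatives and adjusted p = 0.71 with an estimated correlation). That list call was lost without BP-IgG 3, BP-IgG 4 or Ctrl-IgG 2 (camera adjusted p = 0.078, 0.053 and 0.18), and fry did not call it (adjusted p = 0.26). Cell cycle means in log2 CPM were 5.32 and 5.422 in Ctrl-IgG 1 and 2, 5.237 and 5.269 in Ctrl-IgG 3 and 4, and 5.168 to 5.339 with BP-IgG. AURKA lost its call without BP-IgG 2, BP-IgG 3, BP-IgG 4, Ctrl-IgG 1 or Ctrl-IgG 2 (adjusted p = 0.10, 0.086, 0.13, 0.081 and 0.12) and with DESeq2 (0.056), in a range of 0.0090 to 0.13.

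Cytokine and chemokine genes went both ways with BP-IgG, and neither list passed. IL36G, an epidermal interleukin-1 family cytokine, was at 30.7 ± 3.23 against 7.49 ± 1.76 CPM (log2 fold change 2.05, SE 0.14, edgeR adjusted p = 5.9e-07). IL1B (1.24) and its antagonist IL1RN (1.27) rose, and CSF2 fell (-2.58), near the floor with BP-IgG at 0.492 against 3.12 CPM. Among cytokines and alarmins, of 22 measured members, 6 rose and 4 fell (6 and 6 adjusted over the list alone). The other falls were EREG (-0.36), AREG (-0.27) and IL18 (-0.17). CXCL8, the neutrophil chemoattractant interleukin-8, fell (1.33 ± 0.429 against 4.49 ± 1.75 CPM, log2 fold change -1.72, SE 0.30, edgeR adjusted p = 0.0014). Of 10 measured chemokines, CXCL8 (-1.72), CXCL1 (-0.85) and CXCL10 (-2.26) fell and CXCL14 (0.76), CXCL16 (1.05) and CCL20 (0.82) rose, the same counts when adjusted over the list alone (3 and 3). CXCL10 was near the floor, at 0.242 against 1.23 CPM. The chemokine median was -0.22, while their summed CPM was 434 ± 42.7 against 269 ± 19.7 and CXCL14 alone was at 353 ± 43.3 against 208 ± 15.5 CPM. IL6 had 5 expected counts over the 4 Ctrl-IgG libraries and 0 over the 4 BP-IgG libraries, which allows up to 0.0380 CPM, and was not tested. CCL26, an eosinophil chemoattractant, had 0 counts in both groups, which allows up to 0.0380 and 0.0413 CPM. The tests of the cytokine and chemokine lists gave camera adjusted p = 0.41 and 0.96.

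In the IL-17 response list, of 17 measured members, 13 rose and 2 fell (13 and 3 adjusted over the list alone). Its rises included the ammonium transporter RHCG (2.73), lipocalin LCN2 (1.47) and S100A8 (1.49), and its falls were CXCL8 and CXCL1. The list passed (camera adjusted p = 1.1e-05, 2.1e-09 to 2.1e-05 over the other alternatives and adjusted p = 0.39 with an estimated correlation). Its mean log2 CPM was 3.086 and 2.977 in Ctrl-IgG 1 and 2, 3.696 and 3.572 in Ctrl-IgG 3 and 4, and 4.05 to 4.338 with BP-IgG. Among JAK-STAT3 targets, of 15 measured members, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with TIMP1 (0.74), BCL3 (0.82), JUNB (0.60) and SBNO2 (0.41) among the rises and IL4R (-0.25) the fall. This list passed (camera adjusted p = 0.026, 0.0037 to 0.069 over the other alternatives and adjusted p = 0.44 with an estimated correlation), but not without Ctrl-IgG 2 (camera adjusted p = 0.055) or with a stricter low-count filter (0.069). For these targets the mean log2 CPM was 5.137 and 5.071 in Ctrl-IgG 1 and 2, 5.312 and 5.393 in Ctrl-IgG 3 and 4, and 5.476 to 5.624 with BP-IgG. Among NF-kB targets, of 25 measured members, 10 rose and 4 fell (10 and 4 adjusted over the list alone). BCL3 (0.82) and ZC3H12A (0.71) rose with IL1B, and the falls were CXCL8, CXCL1, TRAF1 (-0.82) and ICAM1 (-0.63). The NF-kB list did not pass (camera adjusted p = 0.069), but passed without BP-IgG 1, Ctrl-IgG 3 or Ctrl-IgG 4 (camera adjusted p = 0.031, 0.0063 and 0.045), with no filter, a stricter filter or a length and GC correction (0.025, 0.024 and 0.048) and with the replicate block (0.047), in a range of 0.0063 to 0.19. Among IL-4 and IL-13 response genes, of 14 measured members, 4 rose and 2 fell (5 and 2 adjusted over the list alone), the rises being SOCS1 (1.70), CA2 (1.41), SERPINB13 (1.01) and TNC (0.65) and the falls FETUB (-1.50) and IL4R. The list did not pass (camera adjusted p = 0.097), but passed without BP-IgG 1 or Ctrl-IgG 4 and with a stricter filter (camera adjusted p = 0.045, 0.0495 and 0.019, in a range of 0.019 to 0.14).

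Members of the interferon lists went both ways, and neither list passed. In the type I interferon list, of 39 measured members, 5 rose and 5 fell (5 and 5 adjusted over the list alone): OASL (-2.79), OAS2 (-1.22), HERC5 (-1.11), SP110 (-0.46) and EIF2AK2 (-0.23) fell, and SAMD9 (0.93), ISG15 (0.52), UBE2L6 (0.49), TRIM22 (0.24) and IFITM3 (0.22) rose (camera adjusted p = 0.73). OASL was near the floor, at 0.180 against 1.28 CPM. In the interferon gamma list, of 22 measured members, 6 rose and 3 fell (8 and 3 adjusted over the list alone). Its falls were CXCL10 (-2.26, at 0.242 against 1.23 CPM and so near the floor), CD274 (-0.85) and ICAM1 (-0.63). SOCS1 (1.70) and WARS1 (0.19) were among its rises. The list did not pass (camera adjusted p = 0.13), but passed with no low-count filter (camera adjusted p = 0.042, in a range of 0.042 to 0.19), and fry called it higher (adjusted p = 0.023). In the inflammasome and pyroptosis list, of 16 measured members, 2 rose and 5 fell (4 and 5 adjusted over the list alone): IL1B (1.24) and CASP1 (0.22) rose, and GSDMA (-0.95), NLRP10 (-0.80), IFI16 (-0.22), NLRP1 (-0.21) and IL18 (-0.17) fell (camera adjusted p = 0.28). Complement genes had 4 rises and 0 falls of 13 measured (5 and 0 adjusted over the list alone). These were the C1 proteases C1S (3.23 ± 0.551 against 0.550 ± 0.205 CPM) and C1R (2.27), the C1 inhibitor SERPING1 (0.95), and factor B, CFB (1.3). C1R was low as well, at 3.61 against 0.760 CPM. C1S was lower in Ctrl-IgG 1 (0.246 CPM) than in the other Ctrl-IgG samples (0.626 to 0.692 CPM). The complement list passed (camera adjusted p = 0.0038, 0.0019 to 0.071 over the other alternatives and adjusted p = 0.13 with an estimated correlation), but not with a stricter low-count filter (camera adjusted p = 0.071).

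Antigen presentation genes had 7 rises and 0 falls of 17 measured (10 and 0 adjusted over the list alone). The rises were PSMB9 (0.57) and TAPBP (0.19) and 5 HLA genes, which are not named singly (camera adjusted p = 0.0019, 8.4e-05 to 0.0050 over the other alternatives and adjusted p = 0.33 with an estimated correlation). As a mean log2 CPM, the list was at 4.332 and 4.397 in Ctrl-IgG 1 and 2, 4.483 and 4.535 in Ctrl-IgG 3 and 4, and 4.616 to 4.704 with BP-IgG. PSMB9 lost its call without BP-IgG 1, BP-IgG 2, BP-IgG 3, Ctrl-IgG 1 or Ctrl-IgG 2 (adjusted p = 0.068, 0.081, 0.077, 0.077 and 0.059) and with the replicate block (0.053, in a range of 0.012 to 0.081), and was lower in BP-IgG 4 (4.02 CPM) than in the other BP-IgG samples (5.13 to 5.22 CPM). TAPBP lost its call without BP-IgG 2, BP-IgG 3, BP-IgG 4, Ctrl-IgG 2 or Ctrl-IgG 3, with a length and GC correction and with the replicate block (adjusted p = 0.13, 0.12, 0.073, 0.098, 0.061, 0.13 and 0.061, in a range of 0.012 to 0.13). None of 5 measured genes of the Fc receptor and IgG handling list passed by edgeR over all genes or adjusted over the list alone (0 and 0). FCGRT, the neonatal Fc receptor that recycles IgG, was at 6.11 ± 0.269 against 7.29 ± 0.437 CPM (adjusted p = 0.091, and 0.014 with a length and GC correction, in a range of 0.014 to 0.26). B2M was at 337 ± 7.89 against 303 ± 26.5 CPM (adjusted p = 0.072), and passed without Ctrl-IgG 4 (0.0040), with no low-count filter (0.048) or with voom (0.034), in a range of 0.0040 to 0.20. SYK was at 26.7 ± 1.33 against 25.6 ± 1.197 CPM (adjusted p = 0.52). As a set the Fc list had camera adjusted p = 0.999.

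Proteases and their inhibitors moved in both directions. In the protease, plasminogen and inhibitor list, of 28 measured members, 10 rose and 9 fell (11 and 10 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.73). MMP9, a gelatinase, rose (41.2 ± 11.8 against 9.53 ± 3.55 CPM, log2 fold change 2.13, SE 0.24, edgeR adjusted p = 4.3e-05), as did KLK10 (1.67), TIMP1 (0.74) and CTSV (0.73). PLAU, urokinase, fell (328 ± 29.5 against 486 ± 21.1 CPM, log2 fold change -0.57, SE 0.06, edgeR adjusted p = 3.2e-05), and so did CTSB (-0.50). TGF-beta and matrix genes had 7 rises and 9 falls of 25 measured (7 and 10 adjusted over the list alone). TAGLN (1.05) and TGFBI (0.78) rose, and VIM (-0.96) and SNAI2 (-0.44), a filament gene and a transcription factor of mesenchymal cells, fell. This list did not pass (camera adjusted p = 0.73), and its median (0.10) and mean (-0.03) differ in sign.

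The list of EGFR ligands and MAPK feedback regulators fell in the cells given BP-IgG. Of 18 measured members, 15 fell and 0 rose (0 and 15 adjusted over the list alone), with a median log2 change of -0.45 (camera adjusted p = 5.5e-12, 4.6e-17 to 1.5e-09 over the other alternatives and adjusted p = 0.13 with an estimated correlation). The phosphatase DUSP6 was at 109 ± 9.33 against 267 ± 16.7 CPM (log2 fold change -1.29, SE 0.06, edgeR adjusted p = 4.8e-08). The transcription factor ETV5 (-1.26), the phosphatase DUSP5 (-1.10) and the EGFR inhibitor ERRFI1 (-1.01) fell as well. The 3 members that did not pass were the ligand genes TGFA (-0.12), HBEGF (-0.02) and EPGN (0.04). Of 25 immediate early and AP-1 genes, CCN2 (-1.71), CCN1 (-1.2) and DUSP4 (-0.87) fell with DUSP5 and DUSP6, and FOSL2 (0.68), JUNB (0.60) and BTG2 (0.47) rose (3 and 5 adjusted over the list alone). CCN2 was at 105.4 and 95.6 CPM in Ctrl-IgG 1 and 2 and at 56.9 and 54.4 in Ctrl-IgG 3 and 4. That list did not pass (camera adjusted p = 0.19).

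**Figure D2:**
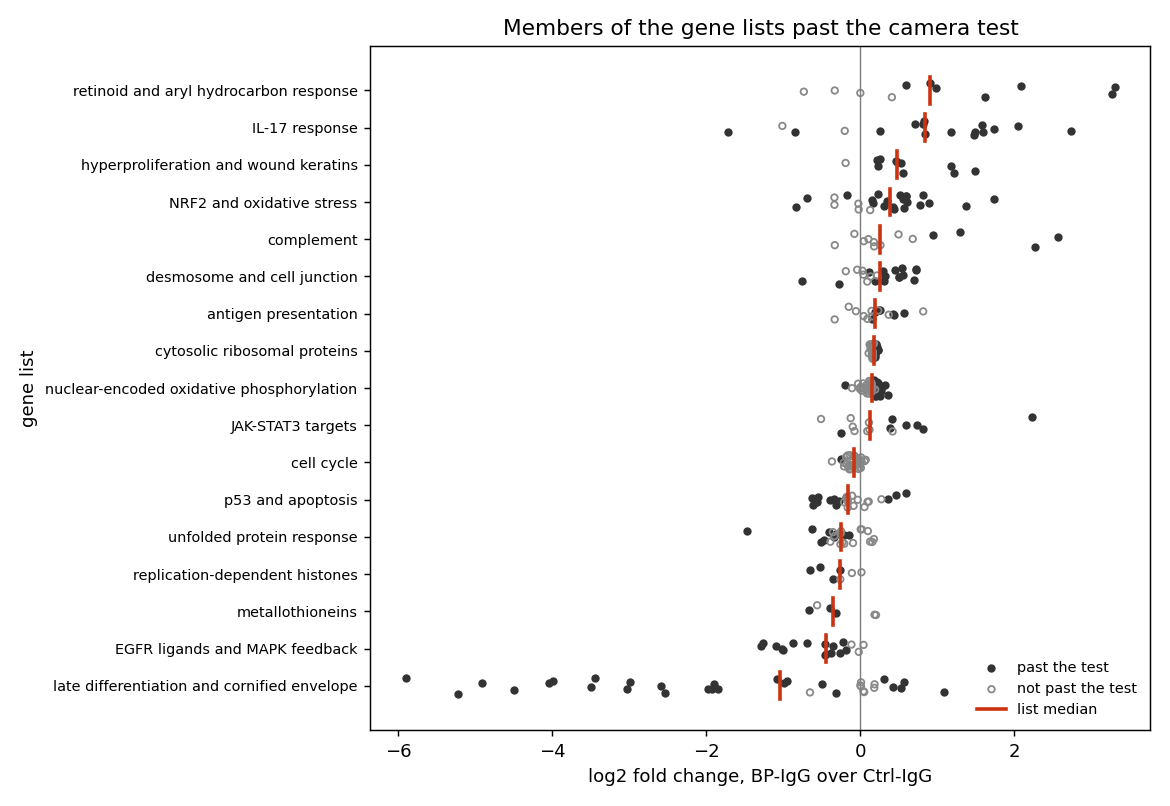
Log2 fold change, BP-IgG over Ctrl-IgG, of each measured member of the 17 gene lists past the camera test, with filled points for members past edgeR's test, open points for the others and a red line at the list median. Medians run from -1.04 for late differentiation to 0.90 for the retinoid and aryl hydrocarbon response, while ribosomal protein genes lie close together around 0.17.

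Oxidative stress genes rose with BP-IgG. In the NRF2 and oxidative stress list, of 26 measured members, 18 rose and 3 fell (18 and 5 adjusted over the list alone). Ferritin chains FTH1 (2419 ± 85.8 against 1307 ± 94.3 CPM, log2 fold change 0.89, SE 0.05, edgeR adjusted p = 2.9e-07) and FTL (0.78) rose, as did AKR1C2 (1.38) and the glutathione peroxidase GPX4 (0.57). The falls were heme oxygenase HMOX1 (-0.84), the cystine transporter SLC7A11 (-0.70) and catalase CAT (-0.18). This list passed (camera adjusted p = 9.2e-07, 1.7e-13 to 3.5e-06 over the other alternatives and adjusted p = 0.13 with an estimated correlation). Retinoid and aryl hydrocarbon response genes had 7 rises and 0 falls of 11 measured (8 and 0 adjusted over the list alone), with a median log2 change of 0.90 (camera adjusted p = 0.00049, 3.7e-06 to 0.0015 over the other alternatives and adjusted p = 0.13 with an estimated correlation). CYP1B1 was at 6.88 ± 1.47 against 0.721 ± 0.169 CPM (log2 fold change 3.27, SE 0.23, chromosome 2, 38066973 to 38109902), and the retinal reductase DHRS3 at 16.9 ± 4.64 against 3.98 ± 0.444 CPM (log2 fold change 2.09, SE 0.19). CYP1A1 (3.31) rose too, from near the floor, at 4.06 against 0.397 CPM. The metallothionein list had 0 rises and 3 falls of 6 measured (1 and 4 adjusted over the list alone), the falls being the metallothioneins MT2A (-0.66) and MT1E (-0.39) and the zinc exporter gene SLC30A1 (-0.32) (camera adjusted p = 0.026, 0.0062 to 0.040 over the other alternatives and adjusted p = 0.37 with an estimated correlation). Metallothionein list means in log2 CPM were 4.928 and 4.99 in Ctrl-IgG 1 and 2, 4.841 and 4.823 in Ctrl-IgG 3 and 4, and 4.582 to 4.778 with BP-IgG.

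In the lists of the unfolded protein response and of p53 and apoptosis more members fell than rose, and 15 and 12 of 24 did not pass. In the unfolded protein response list 0 rose and 9 fell of 24 measured (0 and 9 adjusted over the list alone), including EDEM1 (-0.51), TRIB3 (-0.47), CHAC1 (-1.46) and ASNS (-0.34). The list passed (camera adjusted p = 0.0019, 3.2e-05 to 0.0099 over the other alternatives and adjusted p = 0.34 with an estimated correlation), with a mean log2 CPM of 7.128 and 7.154 in Ctrl-IgG 1 and 2, 6.953 and 6.958 in Ctrl-IgG 3 and 4, and 6.713 to 6.901 with BP-IgG. In the p53 and apoptosis list, of 24 measured members, 3 rose and 9 fell (4 and 10 adjusted over the list alone). BCL2L1 (-0.56), TNFRSF10B (-0.34), RRM2B (-0.39) and GADD45B (-0.61) fell, and GADD45A (0.35), BTG2 (0.47) and BCL2L11 (0.59) rose (camera adjusted p = 0.014, 0.0029 to 0.046 over the other alternatives and adjusted p = 0.42 with an estimated correlation). For p53 and apoptosis the mean log2 CPM was 5.676 and 5.678 in Ctrl-IgG 1 and 2, 5.849 and 5.845 in Ctrl-IgG 3 and 4, and 5.613 to 5.695 with BP-IgG, so that Ctrl-IgG 1 and 2 lay within the BP-IgG range. BCL2L1 codes for an anti-apoptotic protein and TNFRSF10B for a death receptor. Heat shock genes had 3 rises, HSPB1 (1.0), CRYAB (0.88) and DNAJB1 (0.41), and 5 falls, DNAJB4 (-0.57), DNAJA1 (-0.31), HSP90AA1 (-0.27), CHORDC1 (-0.26) and HSPA1A (-0.26), of 15 measured (3 and 5 adjusted over the list alone). That list did not pass (camera adjusted p = 0.59).

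Among metabolic lists, nuclear-encoded oxidative phosphorylation genes rose by small amounts. In that list, of 42 measured members, 19 rose and 1 fell (25 and 1 adjusted over the list alone), with a median of 0.15 (0.11 after a length and GC correction, with 13 members past the test) and NDUFS1 (-0.20) as the fall (camera adjusted p = 1.3e-06, 5.1e-11 to 0.00043 over the other alternatives and adjusted p = 0.44 with an estimated correlation). The mean log2 CPM there was 5.96 and 6.076 in Ctrl-IgG 1 and 2, 6.064 and 6.148 in Ctrl-IgG 3 and 4, and 6.182 to 6.26 with BP-IgG. NDUFB3 (0.36), NDUFS8 (0.27) and NDUFB10 (0.24) were among the rises, but NDUFB10 was not past the test after a length and GC correction (adjusted p = 0.099, in a range of 0.0019 to 0.099). In the hypoxia and glycolysis list, of 26 measured members, 10 rose and 6 fell (12 and 6 adjusted over the list alone). ADM (1.54), NDRG1 (0.78) and SLC2A1 (0.99) rose and ANGPTL4 fell (-1.77). The list did not pass (camera adjusted p = 0.052), but passed without BP-IgG 1, BP-IgG 3, Ctrl-IgG 2 or Ctrl-IgG 4 and with no filter (camera adjusted p = 0.045, 0.048, 0.030, 0.0495 and 0.0012, in a range of 0.0012 to 0.089). In the lysosome and autophagy list, of 25 measured members, 10 rose and 3 fell (11 and 3 adjusted over the list alone). CTSD (0.88) and NPC2 (0.31) rose and CTSB (-0.50), NPC1 (-0.29) and ATG7 (-0.24) fell. That list did not pass (camera adjusted p = 0.054), but passed without Ctrl-IgG 4 and with no filter (camera adjusted p = 0.035 and 0.0044, in a range of 0.0044 to 0.11). Of 25 cholesterol biosynthesis genes, 3 rose and 4 fell (3 and 6 adjusted over the list alone), among them PMVK (0.38) and SREBF2 (0.18) upward and IDI1 (-0.30) and MSMO1 (-0.17) downward. The cholesterol list did not pass (camera adjusted p = 0.23), but passed without Ctrl-IgG 3 (0.046, in a range of 0.046 to 0.54).

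Few markers of fibroblasts, melanocytes, endothelial cells and leukocytes had enough counts to be tested. Of the Merkel cell and sweat gland markers, only 4 keratins had enough. Of 14 fibroblast markers, 7 could be tested, and FAP (0.65), FBLN1 (0.61) and COL1A1 (0.32) rose while 0 fell (3 and 1 adjusted over the list alone). Together the tested fibroblast markers summed to 90.8 ± 3.71 against 67.1 ± 6.16 CPM (camera adjusted p = 0.10, and 0.035 without Ctrl-IgG 1 and 0.044 with no filter, in a range of 0.035 to 0.17). COL1A1 lost its call without BP-IgG 1, BP-IgG 3, BP-IgG 4, Ctrl-IgG 2 or Ctrl-IgG 3 and after a length and GC correction (adjusted p = 0.078, 0.085, 0.13, 0.10, 0.10 and 0.068, in a range of 0.0015 to 0.13). The single melanocyte marker tested, MITF, was at 6.95 ± 0.484 against 8.41 ± 0.649 CPM (adjusted p = 0.075, 0 and 1 adjusted over the list alone). Of 2 endothelial markers tested, ROBO4 fell (2.93 ± 1.0 against 9.66 ± 0.553 CPM), 0 and 1 adjusted over the list alone. The single leukocyte marker tested, ITGAM, was at 1.13 ± 0.301 against 1.22 ± 0.434 CPM (adjusted p = 0.90, 0 and 0 adjusted over the list alone). These 3 lists had too few measured members for camera. Of 12 Merkel cell and sweat gland markers, the 4 tested were keratins. KRT18 (-0.95) and KRT8 (-0.39) fell and KRT7 (0.74) and KRT19 (1.23) rose (2 and 2 adjusted over the list alone). KRT20, ATOH1, SCGB2A2 and DCD had 0 expected counts in both groups, and CHGA, SYP, AQP5 and MUCL1 had too few to test. The 4 keratins summed to 565 ± 35.4 against 683 ± 84.6 CPM, and the list did not pass (camera adjusted p = 0.60).

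Lists that follow RNA and library quality also moved. Cytosolic ribosomal protein genes had 22 rises and 0 falls of 38 measured (36 and 0 adjusted over the list alone), with a median of 0.17 and, after a length and GC correction, of 0.11 with 10 members past the test (camera adjusted p = 3.9e-10, 2.2e-26 to 3.3e-06 over the other alternatives and adjusted p = 0.44 with an estimated correlation). RPS3 (0.22), RPS20 (0.21), RPL18 (0.20) and RPS29 (0.20) were among these. Ribosomal means in log2 CPM were 8.901 and 9.071 in Ctrl-IgG 1 and 2, 9.075 and 9.182 in Ctrl-IgG 3 and 4, and 9.203 to 9.269 with BP-IgG, and without Ctrl-IgG 1 the median was 0.1122. RPS29 lost its call without BP-IgG 1 (adjusted p = 0.056), and RPL18 and RPS29 after a length and GC correction (0.081 and 0.13), in ranges of 0.0016 to 0.081 and 0.0033 to 0.13. Replication-dependent histone genes had 0 rises and 4 falls of 7 measured (0 and 4 adjusted over the list alone), H2BC4 (-0.65), H4C8 (-0.52), H2AC6 (-0.36) and H2BC5 (-0.26) (camera adjusted p = 0.026, 0.0029 to 0.051 over the other alternatives and adjusted p = 0.39 with an estimated correlation). That list was lost without Ctrl-IgG 4 (camera adjusted p = 0.051). H2AC6 lost its call without BP-IgG 2 (0.057, in a range of 9.3e-05 to 0.057). H4C8 lost its call without BP-IgG 2, BP-IgG 3 or Ctrl-IgG 1 (0.063, 0.066 and 0.057, in a range of 0.0096 to 0.066), and H2BC5 without BP-IgG 2, BP-IgG 4, Ctrl-IgG 3 or Ctrl-IgG 4 (0.052, 0.075, 0.053 and 0.066) and with the replicate block (0.062, in a range of 0.0067 to 0.075). Of 15 mitochondrially encoded genes, MT-CO1 (0.21), MT-ND4 (0.19), MT-ND4L (0.17) and MT-RNR1 (0.15) rose and MT-ND1 fell (-0.27), 4 and 3 adjusted over the list alone. Their list did not pass (camera adjusted p = 0.65), but passed with no filter (0.048, in a range of 0.048 to 0.99). MT-ND1 lost its call without BP-IgG 2 (0.051, in a range of 3.6e-07 to 0.051). MT-ND4L lost its call without BP-IgG 1, BP-IgG 2, BP-IgG 3, Ctrl-IgG 1 or Ctrl-IgG 2 (0.077, 0.068, 0.057, 0.059 and 0.069) after a length and GC correction (0.25) and with the replicate block (0.053), in a range of 0.0029 to 0.25. Mitochondrial transcripts made up 7.81% to 8.89% of counts, highest in Ctrl-IgG 4, which was also the shallowest library.

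The first principal component, with 45.3% of the variance, parted BP-IgG from Ctrl-IgG samples, and the other main component (13.1%) set Ctrl-IgG 1 (21.78) apart from Ctrl-IgG 4 (-31.97). All replicate pairs differed by more than sampling noise, with chi-square per degree of freedom of 2.78 to 14.1. The controls parted into 2 pairs: Ctrl-IgG 1 or 2 against Ctrl-IgG 3 or 4 gave 11.4 to 14.1, while Ctrl-IgG 1 against 2 and 3 against 4 gave 4.79 and 4.69. Without Ctrl-IgG 1 and 2, 2467 genes and 18 lists were called, and without Ctrl-IgG 3 and 4, 4326 genes and 20 lists. Of the 38 lists tested, 10 were called higher and 7 lower by camera with its preset correlation, and with an estimated correlation camera called 0, with 6 at an unadjusted p under 0.05. The rotation test fry called 24 lists, but it tests whether a list's genes move on balance in a single direction and does not compare them with other genes. It did not call the cell cycle list and called 8 that camera did not: cytokines, interferon gamma, IL-4 and IL-13, immediate early, hypoxia, lysosome, fibroblast and Merkel cell. Median, mean and camera direction differed in sign for the TGF-beta, Fc receptor, heat shock and Merkel cell lists, and fry's direction was opposite to camera's for the TGF-beta, Fc receptor, heat shock and chemokine lists. On the TPM scale the median flipped sign for 5 lists that did not pass: lysosome, proteases, TGF-beta, Fc receptors and mitochondrially encoded genes. Among called genes named here, the 4 samples of a group lay on the same side of the other group, except for AURKA, CCL20, CHORDC1, COL1A1, DSG1, EREG, H2AC6, HSPA1A, ICAM1, KLK7, KRT19, LAMA3, MSMO1, MT-ND1, MT-RNR1, NLRP1, PSMB9 and TRIM22.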

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

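The test of fewer committed keratinocytes and the aryl hydrocarbon receptor test were chosen after the results they measure were seen, and the margin of 1 SE used to decide each length and GC test and the thinning test was set after their medians were seen. Without a margin, the length and GC tests of the ribosomal and oxidative phosphorylation rises would have counted against such a trend. With a margin of 2 SE, used first, the thinning test fell short of its bound, and at either margin it cannot decide on depth. In 13 of 398 groups of 4 values, a single sample stood far from the other 3, where chance alone gives about 5% of groups, and 5 of the 13 were in BP-IgG 1. In BP-IgG 1, IGFBP3 was at 12.4 CPM (others 11 to 11.2), TNC at 161.5 (others 187.6 to 192.7) and MT-ND1 at 4000 (others 3658 to 3708). The mean log2 CPM of the NF-kB list was 4.129 in BP-IgG 1 (others 4.252 to 4.268), and that of the mitochondrially encoded list 11.67 (others 11.57 to 11.58). H2BC4 was at 9.368 CPM in BP-IgG 3 (others 6.66 to 7.09), and PSMB9 at 4.016 in BP-IgG 4 (others 5.13 to 5.22). C1S was at 0.2461 CPM in Ctrl-IgG 1 (others 0.626 to 0.692), and the mean log2 CPM of the hypoxia list was 6.885 there (others 6.899 to 6.90). The protease list stood at 5.235 in Ctrl-IgG 2 (others 5.294 to 5.301), and HRNR at 27.69 CPM in Ctrl-IgG 3 (others 21.6 to 22.4). MT-ND4 was at 12510 CPM in Ctrl-IgG 4 (others 11060 to 11260), and this library had 12670000 counts in total (others 19750000 to 20340000).

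Of the 35 splits of the 8 samples into 4 and 4, only the real split called as many as 3363 genes (highest other split 0). A share of 1 in 35 is the lowest this test can give, so it cannot exclude chance. Every other split mixes the groups and adds their difference to the spread, so few calls there say little about what made the groups differ. For the number of lists called by camera chance cannot be excluded, since 2 of the 35 splits gave as many as the real 17 and the highest other gave 19. That split set BP-IgG 1 with Ctrl-IgG 1, Ctrl-IgG 2 and Ctrl-IgG 3. It thus kept part of the real contrast, so the splits are not a clean measure of chance for the lists.

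Late differentiation genes fell by a median log2 change of 1.04 while early ones went both ways. Against a gene length or GC trend as the whole cause, the late median was -1.1489 after a correction fitted without the list. The SE of the group difference in the list mean, taken without the correction, was 0.081. Against reads moved between LCE copies, the log2 ratio of CPM summed over all 18 LCE genes was -2.7577. As to fewer committed keratinocytes, 7 early members rose and 3 fell, and the early list median was 0.16. The SE of the group difference in the early list mean was 0.14. The falls were KRT10, DSC1 and DSG1, and the list did not pass (camera adjusted p = 0.086), so this count cannot decide the question. Fewer committed keratinocytes, a smaller share of terminally differentiated cells, a response to the patient IgG and a difference between IgG preparations remain open.

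Ribosomal protein and oxidative phosphorylation genes rose as lists by small amounts, with medians of 0.17 and 0.15. Both list calls were lost with an estimated correlation (camera adjusted p = 0.44 for each). After a length and GC correction the medians were 0.1056 and 0.1137, lower than before, with 10 and 13 members past the test against 22 and 20. The SEs of the group difference in list mean, 0.0597 and 0.0426, were taken without the correction, so the spread after it is not known. Both medians lay within 1 such SE of bounds set before the correction but after the uncorrected medians were seen. Such a trend can therefore not be told apart from a real rise. After thinning every library to the shallowest total the ribosomal median was 0.1716, against 0.1739 before, while the genes called went from 3363 to 3003. The SE of the group difference in the thinned list mean was 0.0589. Thinning leaves ratios of such abundant genes nearly unchanged whatever made them differ, so it cannot decide on library differences that go with depth. Ctrl-IgG 1 was lowest of the controls in both lists and Ctrl-IgG 4 highest, and without Ctrl-IgG 1 the medians were 0.1122 and 0.1147. A biological rise with BP-IgG was not tested beyond this.

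The retinoid and aryl hydrocarbon list rose, a call lost with an estimated correlation (camera adjusted p = 0.13), and the source of that rise stays open. Of 9 further retinoid-responsive genes tested, 4 rose and 2 fell with a median log2 change of 0.0574. The SE of the group difference in their mean log2 CPM, which is not the spread of the median, was 0.058. The median lay between the values that would have spoken for and against retinoid receptor activation. TIPARP, a feedback target of the aryl hydrocarbon receptor, had a log2 change of 6e-04 (SE 0.0468, edgeR adjusted p = 0.997) while CYP1A1 rose by 3.31. This rests on 1 gene because AHRR was too low to test. AHRR had 20.83 expected counts over the BP-IgG libraries and 20 over the Ctrl-IgG libraries. A substance carried over with the IgG preparations of one group may also account for the rise, and 0 of the samples analysed here lacked IgG, so it cannot be told apart from the patient IgG itself.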

How the results depend on the processing

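The length and GC correction and the fits without 2 controls were added after seeing the data, the other alternatives were planned. Of the 3363 genes called, 967 changed by at least 1.5-fold, a bound that by construction can only remove calls, and limma-trend on log2(TPM + 1) called 2075, of which 1767 were among the 3363 and the cause was not tested. The count was 3215 to 3633 under the other filters and RLE scaling, 3265 with DESeq2, 3562 with voom, 4424 at an adjusted p under 0.10, 3424 after the length and GC correction, 2453 to 3780 with a sample left out, and 2467 and 4326 without Ctrl-IgG 1 and 2 or 3 and 4. The 17 lists called by camera became 0 with an estimated correlation (6 at an unadjusted p under 0.05, lowest adjusted p 0.13), while fry called 24, and 16 to 21 were called with a sample left out and 18 and 20 with these controls left out. With the replicate block 2914 genes (2821 of them shared) and 18 lists were called. Same-numbered samples deviated together with correlations of -0.01, 0.051, 0.104 and 0.03, and 3 of 4 samples correlated best with their own number, and no label says that a number pairs samples. The replicate block ended the calls of COL17A1, PSMB9, TAPBP, H2BC5 and MT-ND4L (adjusted p = 0.051, 0.053, 0.061, 0.062 and 0.053) and made those of DST (0.0086) and the NF-kB list (0.047), and it changed no other call among the 157 genes the naming rule took or the lists. Of 151 called genes followed singly, 12 lost the call in at least 1 fit with a sample left out. No list and none of these genes past the test reversed direction under the alternatives computed for them, and the other genes named in the text were not followed under alternatives. In simulated data only 16% of 1.2-fold changes were recovered, but 164 genes were called there against 3363 here. With fewer changed genes the adjusted p asks for a smaller unadjusted p, so this share does not give the recovery in these data.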

Other observations

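The tests on further ERK and YAP genes were written before their values were seen, and no test of this part was chosen after. A margin of 1 SE was added to them later and changed neither outcome. Beyond the lists, keratins of mucosal or simple epithelia moved in different directions: KRT13, a partner of KRT4 in oral epithelium, was at 42.8 against 8.45 CPM (log2 fold change 2.38, SE 0.29, edgeR adjusted p = 8.4e-05), next to the rises of KRT4, KRT7 and KRT19 and the falls of KRT8 and KRT18. The retinoic acid receptor gamma gene, RARG, was at 129 against 62.8 CPM (1.04, SE 0.13), and GPRC5A, an orphan receptor induced by retinoic acid, at 35.7 against 17.5 CPM (1.01, SE 0.19). The transglutaminase TGM2 fell from 25.65 to 13.03 CPM (-0.97, SE 0.13), and the ectonucleotidase NT5E fell from 306 to 160 CPM (-0.93, SE 0.07). STRA6, a retinol transporter, had 42 expected counts over the BP-IgG libraries and 2 over the Ctrl-IgG libraries and was not tested. These genes were chosen after their values were seen.

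Lower ERK output is a hypothesis for the fall of the EGFR ligand and MAPK feedback list. Of 12 further ERK-dependent genes tested, 4 rose and 5 fell, with a median log2 change of -0.1347. The SE of the group difference in their mean log2 CPM, which is not the spread of the median, was 0.0374. The median was short of the bound of -0.2 set beforehand but below 0, so the test leaves lower ERK output open. EPHA4, KCNN4, LZTS1 and EMP1 rose (0.47, 1.37, 1.16 and 0.42), and EPHA2, ETV1, MAP2K3, SH2B3 and ELK3 fell (-0.19, -1.32, -0.33, -0.55 and -0.20).

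Lower YAP and TEAD output is a hypothesis for the fall of CCN1 and CCN2. Of 14 further YAP target genes tested, AMOTL2 rose (0.16) and 7 fell, including NT5E, AXL (-0.67), FJX1 (-0.52) and ASAP1 (-0.47). Their median log2 change was -0.1916, and the SE of the group difference in their mean log2 CPM was 0.0476. The median was close to the bound of -0.2 set beforehand without reaching it, so the test leaves lower YAP and TEAD output open too.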
